A study of Homo sapiens and Mus musculus with 34 samples.

How the data were processed

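RNA abundance was measured on Affymetrix human and mouse transcriptome arrays, from 100 ng of total RNA per array purified with RNeasy kits and labelled with the WT PLUS kit. The human part holds 24 arrays, 3 untreated and 3 CYC065-treated from each of the lines Kelly, SKNAS, BE2C and SHSY5Y, in 2 deposits: an earlier one (Kelly and SKNAS) and a later one (BE2C and SHSY5Y). The mouse part, from the earlier deposit, holds 6 untreated and 4 treated TH-MYCN tumors, each from its own animal. Cells were treated for 1 h with 1 µM, except that the treatment protocol gives 5 µM for SKNAS where its sample labels give 1 µM. Mice received 50 mg/kg and tumors were taken at 6 h. The controls are called untreated in the labels and DMSO or vehicle in the design text, and the conflict is left open. That Kelly and BE2C carry an amplified MYCN gene and the other lines do not is general knowledge about these lines.

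The deposited values are log2 summaries per row of the array, made by the authors with RMA; the labels name RMA, affy and limma without a version or a role for each. RMA scales arrays to a common distribution and can so hide a global change in RNA content. The deposited arrays do not share one distribution: the median over all rows was 4.54 to 4.58 on untreated and 4.69 to 4.75 on treated tumor arrays, and 4.62 to 4.94 on human arrays. Fold changes are differences of the deposited values. The raw intensity files were not used here. The authors' table gives, for BE2C and SHSY5Y, a log2 fold change, a mean log2 level, a p-value and an adjusted p-value per gene symbol, as named by the authors in its columns. All array columns were matched to a sample.

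The human value table names its rows by probe cluster only. Symbols were therefore joined by value: a symbol of the authors' table was given to the row, or the pair of rows, whose fold changes and mean levels in BE2C and SHSY5Y equal the 4 values of the table within 1e-07. Of 33720 symbols, 26741 matched 1 row and 4113 the mean of 2 rows, together 30854 (91.5%); 101 shared a row with another symbol, 1 was ambiguous, 2751 had no match and 13 had been turned into dates. A reference table of genes, which holds 24888 of the 33720 symbols, was used to narrow the search for pairs of rows to a chromosome. As a negative control, the same searches with the SHSY5Y values moved to other symbols gave 0 matches to 1 row and 0 to pairs of rows. Where a symbol had 2 rows the brighter was used. The mouse rows could not be named, and the tests were made on 65956 rows other than controls.

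Each line was tested by limma 3.58.1 (R 4.3.3) with group means and moderated variances, treated against untreated, 3 arrays against 3. A fit of 8 group means to all 24 arrays gave the average over the lines and an F test of any difference between lines. It also gave the difference between the amplified lines and the others, with the pairs within each deposit. Untreated levels were compared in a separate fit of 4 group means to the 12 untreated arrays. Tumors were tested 4 against 6. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Errors after ± are moderated standard errors for changes and SDs for levels. Single summaries of arrays (background, control and median rows) were compared by two-sided exact permutation of the arrays, adjusted over 12 tests. A total of 40 gene lists with at least 5 measured members was tested by camera with a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. Lists were not tested in the tumors, and human and mouse changes were not compared gene by gene.

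The genes named were set by a rule: in each comparison the 10 largest rises and the 10 largest falls among called genes whose treated arrays all lie beyond all untreated ones (a condition not used for the difference between lines), leaving out symbols of small RNA genes, antigen and odorant receptor genes, LOC, LINC, Gm and Rik names and numbered open reading frames. The rule added up to 4 members of each list described and a set of fixed genes, among them MYCN, MYC, MAX, MCL1, BCL2, CDK9, CCNT1, HEXIM1, HAND2, GATA3, FOS, JUN, EGR1, POLR2A, CDKN1A, CDK2, CCNE1, GAPDH and ACTB. Some rises that the rule names are left out of the text because the call was lost without a single array, and some genes and 1 list are not reported here.

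Precision on arrays comes from replicates and from signal over background. Replicate arrays of a line correlated at r of at least 0.994 and tumors at 0.975 to 0.996. The fits were tested on simulated data with 200 changed genes, 50 at each fold except in the F test. At 2-fold, 96.0% were recovered with the spread of Kelly, 96.0% of SKNAS, 88.0% of BE2C, 84.0% of SHSY5Y and 90.0% of the tumors, with 7, 6, 4, 3 and 7 false calls. At 1.25-fold 38.0%, 18.0%, 26.0%, 10.0% and 6.00% were recovered. In these fits the noise was independent between genes and no whole array was shifted. The false calls therefore do not carry over to the real tumors, where the median row shifted and most rows were called. For the average, the difference between amplified and other lines and the F test, 100%, 98.0% and 94.0% were recovered at 2-fold, with 12, 11 and 11 false calls.

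Alternatives were other scalings (median, housekeeping genes, quantile normalisation), dim genes left out, all rows, the mean of the rows of a symbol, trend and robust variances, array weights, a spread shared over all 24 arrays, a fold of at least 1.5, each deposit alone and each replicate left out. Cyclic loess, rows above background, identical rows counted once, quantile normalisation before the list tests and replicates left out of the list tests were added after seeing the data. Rows above background were tumor rows whose mean level was above that of nearly all of the 23 background rows. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.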

Results

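RNA abundance was measured on Affymetrix transcriptome arrays in 4 human neuroblastoma lines and in neuroblastomas of TH-MYCN mice, which carry a MYCN transgene in cells of the sympathetic lineage. Each line contributed 3 untreated arrays and 3 arrays of cells given CYC065, an inhibitor of cyclin-dependent kinases, for 1 h, which makes 24 human arrays. The mouse part held 6 untreated tumors and 4 tumors taken 6 h after a dose of 50 mg/kg. Kelly and BE(2)-C (BE(2)C in the sample labels, BE2C here) are lines with an amplified MYCN gene, and SK-N-AS (SKNAS) and SH-SY5Y (SHSY5Y) are lines without that amplification. The dose was 1 µM in Kelly, BE2C and SHSY5Y, while for SKNAS the sample labels give 1 µM and the treatment protocol 5 µM. Replicate arrays of a group correlated at r between 0.994 and 0.999 across genes, and the number of arrays, not a count of molecules, limits the precision.

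The untreated lines were compared to ask how they differed in MYCN and its relative MYC, both transcription factors that drive growth genes. MYCN was 50.7-fold higher in Kelly than in SKNAS (11.74 ± 0.01 against 6.07 ± 0.20, mean log2 value ± SD, n = 3). It was 28.9-fold higher in BE2C than in SHSY5Y (11.72 ± 0.08 against 6.86 ± 0.10). MYC went the other way, 2.95-fold lower in Kelly than in SKNAS and 3.68-fold lower in BE2C than in SHSY5Y. The limma adjusted p was 1.12e-14 and 3.59e-13 for MYCN and 7.16e-11 and 4.81e-11 for MYC. Lines measured in different deposits were not compared in level.

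The 4 lines were compared for what they share after CYC065. Some members of the sympathetic lineage regulators, of the feedback inhibitors of growth factor signalling and of the zinc finger genes fell in every line, and some copies of spliceosomal small nuclear RNA genes rose in every line. GATA3, a factor of sympathetic neurons, fell by 1.73 ± 0.06 in Kelly, 0.86 ± 0.07 in BE2C and 1.48 ± 0.07 in SHSY5Y (log2 change ± SE, n = 3 arrays per group, here and below), and 2.82-fold in SKNAS. MCL1, an antiapoptotic protein with a short-lived transcript, fell by 1.17 ± 0.07, 0.94 ± 0.06, 0.66 ± 0.05 and 0.96 ± 0.08 in Kelly, SKNAS, BE2C and SHSY5Y. KLF6, an immediate early factor, fell by 1.92 ± 0.14, 2.11 ± 0.07, 0.90 ± 0.07 and 1.63 ± 0.08, and NFKBIA, the inhibitor of NF-kB, fell by 1.17 ± 0.07, 1.64 ± 0.07, 1.53 ± 0.05 and 1.33 ± 0.09. Of 30854 genes, 584 were lower in all 4 lines at an adjusted p under 0.05, where independent calls would give 0.253, and 49 were higher in all 4 lines, where independent calls would give 0.00135. The 584 held 149 genes named ZNF or ZFP, 430 other genes, 3 microRNA genes and 2 small nucleolar RNA genes. The 49 held 45 small nuclear RNA genes, the Cajal body RNA genes SCARNA7 and SCARNA17, C12orf57 and KLF7-IT1, an intronic transcript of KLF7; SCARNA7, SCARNA17 and C12orf57 were named after their values were seen. Fold changes of pairs of lines correlated across genes at Pearson r between 0.566 and 0.724 and Spearman rho between 0.350 and 0.441, over 6 pairs, and genes are not independent replicates. Among genes called in both lines of a pair, 99.1% to 100% changed in the same direction, and 22 genes were called in opposite directions in some pair of lines. In a fit over all 24 arrays, 9162 genes changed on average over the lines, 4958 higher and 4204 lower, of which 15 were higher and 96 lower by at least 2-fold. With dim genes left out 2958 were higher and 3814 lower. The average over the later deposit alone (BE2C and SHSY5Y) gave 2940 genes, 643 higher and 2297 lower, and adding a fold of at least 1.5 left 612.

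**Figure D1:**
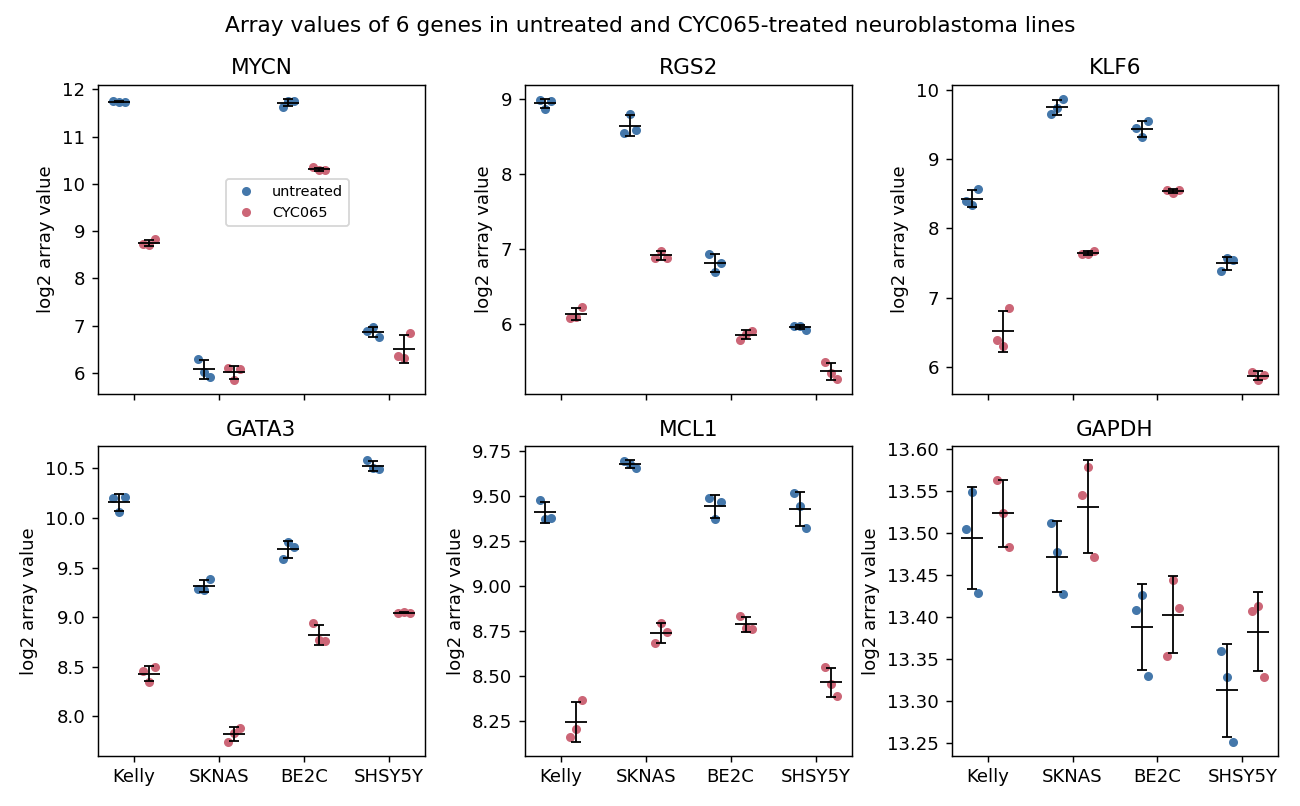
Log2 array values (vertical axes) of MYCN, RGS2, KLF6, GATA3, MCL1 and GAPDH in untreated and CYC065-treated cells of the 4 lines (horizontal axis). Points are arrays, bars are the mean and SD of 3 arrays, and each panel has its own scale that does not start at 0, with GAPDH spanning a far narrower range; RGS2, KLF6, GATA3 and MCL1 lie lower after treatment in all 4 lines, and MYCN fell by 2.98 in Kelly and by 1.41 in BE2C.

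In Kelly the largest fall was that of MYCN itself, 7.91-fold, by 2.98 ± 0.05 with an adjusted p of 6.08e-07, from a mean of 11.74 to 8.75. RGS2, a brake on G protein signalling, fell by 2.81 ± 0.06, INSM2, a neuroendocrine zinc finger factor, by 2.33 ± 0.07, and the mRNA decay factor ZFP36L2 by 2.33 ± 0.08. CCNG2, a cyclin linked to growth arrest, fell by 2.22 ± 0.06, the protocadherin PCDH18 by 2.22 ± 0.06, the zinc finger gene ZNF134 by 2.15 ± 0.10 and KBTBD8, an adaptor of an ubiquitin ligase, by 2.14 ± 0.07. NFE2L3, a basic leucine zipper factor, rose by 2.28 ± 0.17, or 4.85-fold, the largest rise outside small RNA genes. KLF7-IT1 rose by 1.05 ± 0.06 and FKSG29 by 1.05 ± 0.09, and most of the further rises were POTE genes such as POTEE (0.97 ± 0.07), whose copies are nearly identical in sequence. Other fixed genes that fell were HEXIM1, the P-TEFb inhibitor (1.14 ± 0.07), the cyclin genes CCNT1 (0.73 ± 0.07) and CCNE1 (0.64 ± 0.06), HAND2 (0.63 ± 0.05), JUN (0.35 ± 0.06) and CDKN1A (0.25 ± 0.05). MYC changed by 0.16 ± 0.05 with an adjusted p of 0.0690, which misses the threshold. In all, 6524 genes changed, 2924 higher and 3600 lower, and 30 were higher and 320 lower by at least 2-fold. More genes were higher than lower after quantile normalisation (3905 and 3435) and with array weights (4299 and 3929). With median centring 1436 were higher and 3593 lower. The count was 4174 without untreated replicate 1 and 1275 with a fold of at least 1.5 required. In 5 groups of genes ordered by level from dim to bright, 532, 587, 577, 574 and 654 were higher. In the same groups 22, 121, 523, 1396 and 1538 were lower, so the falls depended on level far more than the rises. The median levels of the 2 dimmest groups, 2.79 and 3.99, lay below the background rows, which went from 4.54 to 4.69.

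In SKNAS the glycogen regulator PPP1R3C fell most outside small RNA genes, 5.34-fold, by 2.42 ± 0.11 with an adjusted p of 8.20e-06. DUSP6, a phosphatase that restrains ERK, fell by 2.16 ± 0.06, the feedback inhibitor SPRY1 by 2.02 ± 0.06, KLF6 by 2.11 ± 0.07 and the polo-like kinase gene PLK2 by 1.94 ± 0.07. HAS2, which makes hyaluronan, fell by 1.88 ± 0.10, RGS2 by 1.73 ± 0.08, and the zinc finger genes ZNF92, ZNF134 and ZNF416 by 1.99 ± 0.16, 1.89 ± 0.06 and 1.86 ± 0.08. MYC fell by 0.40 ± 0.06, JUN by 0.70 ± 0.06, HEXIM1 by 0.75 ± 0.07 and CCNT1 by 0.56 ± 0.07. MYCN changed by -0.06 ± 0.11 (adjusted p 0.814) and HAND2 by -0.22 ± 0.06 (adjusted p 0.0733). The vault RNA gene VTRNA1-1 rose by 1.37 ± 0.21, VTRNA1-3 by 0.79 ± 0.09 and KLF7-IT1 by 0.88 ± 0.09. NFE2L3, which rose in Kelly, fell here by 1.32 ± 0.13. In all, 1968 genes changed, 450 higher and 1518 lower, and 43 were higher and 133 lower by at least 2-fold. The count was 1254 without untreated replicate 2, 1261 without untreated replicate 3 and 667 with a fold of at least 1.5 required.

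In BE2C the largest fall outside small RNA genes was that of NFKBIA, 2.89-fold, by 1.53 ± 0.05 with an adjusted p of 0.000118. The translation factor gene EIF5 fell by 1.44 ± 0.05, MYCN by 1.41 ± 0.06 (2.65-fold, from 11.72 to 10.31), and the Notch target HES1 by 1.37 ± 0.15. PCDH18 fell by 1.32 ± 0.05, the phosphatase regulator PPP1R10 by 1.29 ± 0.05, and the zinc finger genes ZNF226 and ZNF792 by 1.37 ± 0.10 and 1.29 ± 0.06. CCNT1 fell by 0.52 ± 0.05, while HEXIM1 changed by -0.21 ± 0.08 (adjusted p 0.249), HAND2 by -0.16 ± 0.05 (adjusted p 0.173) and MYC by 0.11 ± 0.05 (adjusted p 0.344). NFE2L3 rose by 1.06 ± 0.06, KLF7-IT1 by 0.89 ± 0.11, and the noncoding transcripts RP11-187C18.5 and RP11-149F8.5 by 0.91 ± 0.12 and 0.76 ± 0.06. In all, 1253 genes changed, 226 higher and 1027 lower, and 18 were higher and 46 lower by at least 2-fold. The count was 556, 645 and 533 without untreated replicates 1, 2 and 3, and 772 and 775 without treated replicates 5 and 6. It was 2112 with the spread shared over all 24 arrays and 332 with a fold of at least 1.5 required.

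In SHSY5Y PPP1R15B, a regulator of eIF2 phosphorylation, fell 4.93-fold, by 2.30 ± 0.10, the splicing kinase CLK1 by 2.08 ± 0.11, DUSP6 by 2.05 ± 0.11 and the antiproliferative gene TOB1 by 1.80 ± 0.10. TXNIP, which binds thioredoxin, fell by 1.80 ± 0.10, the DNA-binding protein gene PURB by 1.82 ± 0.14, and ZNF134, ZNF92 and ZNF830 by 1.98 ± 0.09, 1.89 ± 0.13 and 1.88 ± 0.07. MYC fell by 1.07 ± 0.09, HAND2 by 0.60 ± 0.07, HEXIM1 by 0.59 ± 0.09 and CCNT1 by 0.77 ± 0.09. For MYCN in SHSY5Y the change was -0.37 ± 0.14 (adjusted p 0.268), and without treated replicate 6 it was -0.54 with an adjusted p of 0.0206. KLF7-IT1 rose by 1.12 ± 0.14, the nuclear noncoding RNA NEAT1 by 0.99 ± 0.12, the respiratory chain gene COX6C by 0.59 ± 0.09 and the splicing factor gene LUC7L3 by 0.51 ± 0.08. In all, 1459 genes changed, 133 higher and 1326 lower, and 10 were higher and 145 lower by at least 2-fold. The count was 889 and 892 without untreated replicates 1 and 2, and 842 and 947 without treated replicates 5 and 6. It was 2799 with a shared spread, 4815 with array weights and 628 with a fold of at least 1.5 required.

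A few of the genes fixed for every line moved little or rested on single arrays. BCL2 in Kelly fell by 0.34 ± 0.09 with an adjusted p of 0.0343, and the adjusted p rose to between 0.0520 and 0.0996 without untreated replicate 1, 2 or 3 or treated replicate 4 or 5. EGR1 in BE2C fell by 0.41 ± 0.06 and EGR1 in SHSY5Y by 0.40 ± 0.09. Without BE2C untreated replicate 1 or 2 the adjusted p for EGR1 in BE2C was 0.0595 or 0.0505. For EGR1 in SHSY5Y it was between 0.0680 and 0.107 without any single array other than treated replicate 6, and 0.0961 after centring on housekeeping genes. JUN in BE2C fell by 0.41 ± 0.07, with an adjusted p between 0.0512 and 0.0815 without untreated replicate 1, 2 or 3 or treated replicate 6. JUN in SHSY5Y changed by -0.06 ± 0.07 (adjusted p 0.858). CCNE1 in BE2C fell by 0.37 ± 0.05, with an adjusted p of 0.0545 or 0.0529 without untreated replicate 1 or 3. CCNE1 in SHSY5Y fell by 0.41 ± 0.07, with an adjusted p of 0.0552 or 0.0644 without untreated replicate 2 or treated replicate 5. CCNE1 in SKNAS changed by -0.26 ± 0.07 (adjusted p 0.0556), and by -0.31 with an adjusted p of 0.0387 without untreated replicate 1. MAX, CDK9, FOS, POLR2A, CDK2 and GAPDH passed the threshold in none of the 4 limma fits. FOS had a mean level of 5.06 in BE2C and 5.09 in SHSY5Y by the authors' table. The untreated background rows there lay at 4.91 and 4.98, so a fall of FOS could hardly be seen. GAPDH changed by 0.03 ± 0.05, 0.06 ± 0.06, 0.01 ± 0.05 and 0.07 ± 0.07 in Kelly, SKNAS, BE2C and SHSY5Y. ACTB has no row paired with its symbol.

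The following lists were fixed before the data were examined; their counts are given in the order Kelly, SKNAS, BE2C and SHSY5Y, and their camera test is on the average over the lines. Of 28 measured adrenergic transcription factors, which define the noradrenergic state of neuroblastoma, 22, 12, 13 and 14 fell and none rose (23, 14, 18 and 19 adjusted over the list alone). The list shifted down on average (adjusted p = 3.06e-25, and adjusted p = 0.000949 with an estimated correlation). With an estimated correlation its adjusted p in the single lines was 0.139, 0.0897, 0.102 and 0.0423. ISL1, a LIM factor of sympathetic development, fell by 1.63 ± 0.06, 1.44 ± 0.07, 0.82 ± 0.05 and 1.37 ± 0.08, and HAND1 fell by 1.39 ± 0.06 in Kelly, 0.37 ± 0.07 in BE2C and 1.79 ± 0.08 in SHSY5Y. Of 31 mesenchymal transcription factors, markers of the other neuroblastoma state, 9, 7, 4 and 6 fell and 1 rose, in Kelly (9, 9, 6 and 6 fell and 2, 1, 0 and 0 rose adjusted over the list alone). Their shift had an adjusted p of 0.000402, and adjusted p = 0.115 with an estimated correlation. Members that fell in every line include ZNF217, a transcriptional repressor (1.75 ± 0.07, 1.58 ± 0.06, 1.12 ± 0.06 and 1.45 ± 0.07), and SNAI1, which represses epithelial genes (1.26 ± 0.11, 1.10 ± 0.10, 1.09 ± 0.14 and 0.68 ± 0.12). Of 30 sympathoadrenal differentiation genes, which include enzymes and vesicle proteins of catecholamine cells, 3 fell and 2 rose in Kelly and none was called in the other lines. The same counts stood adjusted over the list alone, and their upward shift had an adjusted p of 0.0561, adjusted p = 0.376 with an estimated correlation and 0.00795 after quantile normalisation (preset correlation).

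Signalling response genes were the next group. Of 26 growth factor feedback genes, 19, 15, 8 and 11 fell (21, 16, 11 and 15 fell and 1, 1, 0 and 0 rose adjusted over the list alone) and 1 rose, in Kelly. The list shifted down (adjusted p = 4.23e-17, and adjusted p = 3.18e-05 with an estimated correlation). With an estimated correlation its adjusted p in the single lines was 0.0397, 0.0472, 0.102 and 0.0423. SPRY2 fell by 1.69 ± 0.11, 1.56 ± 0.07, 0.90 ± 0.05 and 1.74 ± 0.07, and DUSP4 by 1.32 ± 0.11, 1.06 ± 0.11, 0.76 ± 0.07 and 0.78 ± 0.10. Of 38 immediate early genes, 17, 17, 11 and 12 fell (19, 22, 16 and 15 fell and 3, 0, 0 and 0 rose adjusted over the list alone) and 1 rose, in Kelly, with adjusted p = 1.05e-15, and adjusted p = 0.0165 with an estimated correlation. BTG2, an antiproliferative gene, fell by 1.58 ± 0.06, 0.42 ± 0.08, 0.55 ± 0.05 and 0.54 ± 0.08. Of 29 TGF-beta, BMP, Notch, Wnt and Hedgehog response genes, 16, 11, 9 and 10 fell (17, 12, 12 and 11 fell and 3, 0, 1 and 0 rose adjusted over the list alone) and 2 rose, in Kelly, with adjusted p = 7.14e-09, and adjusted p = 0.00659 with an estimated correlation. BAMBI, a decoy receptor of TGF-beta, fell by 0.88 ± 0.06, 0.89 ± 0.07, 1.17 ± 0.09 and 1.06 ± 0.07. Of 18 circadian clock genes, 10, 3, 1 and 2 fell and none rose (11, 6, 5 and 7 adjusted over the list alone), with adjusted p = 3.00e-07, and adjusted p = 0.00391 with an estimated correlation. Of 20 hypoxia response genes, 9, 4, 2 and 5 fell (11, 7, 5 and 8 fell and 2, 0, 1 and 0 rose adjusted over the list alone) and 1 rose in Kelly and 1 in BE2C, with adjusted p = 6.15e-05, and adjusted p = 0.0204 with an estimated correlation. Of 25 NF-kB targets, 4, 3, 1 and 1 fell (4, 4, 1 and 2 fell and 2, 0, 0 and 0 rose adjusted over the list alone) and 1 rose, in Kelly. Their shift had an adjusted p of 0.247, with a median of 0.03 and a mean of -0.07, which differ in sign. Of 21 interferon response genes, 2 rose in Kelly and 1 in SKNAS (1 and 0 adjusted over the list alone), and their shift had an adjusted p of 0.337.

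Genes of the transcription machinery, of cell death and of stress responses made up a further set of lists. Of 34 genes of P-TEFb, the 7SK complex and elongation, 12, 5, 4 and 4 fell (15, 5, 7 and 7 fell and 2, 0, 0 and 0 rose adjusted over the list alone) and 1 rose, in Kelly. MEPCE, which caps 7SK RNA, fell by 0.82 ± 0.05, 0.45 ± 0.06, 0.56 ± 0.06 and 0.84 ± 0.07, and the list had adjusted p = 3.38e-06, and adjusted p = 0.117 with an estimated correlation. Of 26 Mediator and other CDK genes, 9, 0, 3 and 5 fell and 2, 1, 0 and 0 rose (9, 1, 4 and 6 fell adjusted over the list alone), with adjusted p = 0.0141, adjusted p = 0.437 with an estimated correlation and 0.125 after quantile normalisation. Of 25 BCL2 family and apoptosis regulators, 9, 3, 3 and 2 fell and none rose (9, 5, 3 and 3 adjusted over the list alone), with adjusted p = 0.000290, and adjusted p = 0.00373 with an estimated correlation. MCL1 was the member with the largest fall in each line. Of 24 ATF4 and unfolded protein response genes, 12, 8, 7 and 8 fell and none rose (13, 8, 9 and 11 fell and 2, 0, 0 and 0 rose adjusted over the list alone), with adjusted p = 1.52e-08, and adjusted p = 0.00350 with an estimated correlation. HERPUD1, a gene of endoplasmic reticulum stress, fell by 1.55 ± 0.06, 0.50 ± 0.06, 0.42 ± 0.05 and 1.58 ± 0.07. Of 30 core spliceosome and splicing regulators, 17, 9, 7 and 5 fell (17, 14, 16 and 11 fell and 1, 2, 0 and 1 rose adjusted over the list alone), while 1 rose in Kelly and 1 in SHSY5Y, with adjusted p = 3.09e-11, and adjusted p = 0.117 with an estimated correlation. The splicing kinases CLK1 and DYRK1A fell in each line, DYRK1A by 0.82 ± 0.06, 0.66 ± 0.07, 0.56 ± 0.05 and 0.99 ± 0.07. Of 19 heat shock genes, 2, 2, 1 and 1 fell and none rose, with the same counts adjusted over the list alone, and their shift had an adjusted p of 0.898; the median was 0.03 and the mean -0.01. DNAJB1 fell by 0.83 ± 0.08, 0.49 ± 0.06, 0.52 ± 0.05 and 0.96 ± 0.11.

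Growth and cell cycle lists came next. Of 13 MYC network genes, 6, 2, 3 and 3 fell and none rose (6, 2, 3 and 4 fell and 2, 0, 0 and 0 rose adjusted over the list alone), with adjusted p = 4.40e-05, and adjusted p = 0.00265 with an estimated correlation. MXD1, a MYC antagonist, fell by 0.88 ± 0.05, 0.45 ± 0.07, 0.40 ± 0.05 and 0.66 ± 0.07. Of 38 MYC targets of ribosome biogenesis and growth, 10, 3, 3 and 2 fell and none rose (11, 4, 7 and 4 fell and 2, 0, 0 and 0 rose adjusted over the list alone), with adjusted p = 0.000221, and adjusted p = 0.309 with an estimated correlation. RRS1, a ribosome assembly factor, fell by 1.42 ± 0.05 in Kelly, 0.62 ± 0.07 in BE2C and 1.01 ± 0.14 in SHSY5Y. Of 33 genes of G1/S and DNA replication, 15, 3, 9 and 8 fell (16, 7, 12 and 12 adjusted over the list alone) and 2 rose, in Kelly, with adjusted p = 1.36e-08, and adjusted p = 0.117 with an estimated correlation. E2F8 fell by 1.49 ± 0.06, 0.65 ± 0.08, 0.68 ± 0.06 and 1.23 ± 0.08. Of 34 G2/M and mitosis genes, 16, 2, 1 and 3 fell and none rose (16, 3, 2 and 6 adjusted over the list alone), with adjusted p = 0.000139, and adjusted p = 0.434 with an estimated correlation. The mitotic kinase AURKA fell by 0.93 ± 0.05 in Kelly and 1.26 ± 0.11 in SHSY5Y. Of 26 genes of homologous recombination and damage signalling, 10, 4, 4 and 3 fell (11, 6, 5 and 4 fell and 4, 1, 0 and 0 rose adjusted over the list alone) and 4 rose, in Kelly, with adjusted p = 0.00214, adjusted p = 0.568 with an estimated correlation and 0.174 after quantile normalisation. PALB2, the partner of BRCA2, fell 2.30-fold in Kelly, and by 1.01 ± 0.07, 0.72 ± 0.05 and 0.98 ± 0.11 in SKNAS, BE2C and SHSY5Y. Of 72 cytosolic ribosomal protein genes, 22 rose in Kelly and 1 fell in SKNAS (29 and 0 adjusted over the list alone), with adjusted p = 2.65e-06, and adjusted p = 0.313 with an estimated correlation. RPS12 rose by 0.27 ± 0.05 in Kelly. Of 36 oxidative phosphorylation genes, 11, 1, 0 and 1 rose and none fell (15, 7, 0 and 1 adjusted over the list alone), with adjusted p = 0.000139, and adjusted p = 0.285 with an estimated correlation. Of 26 stable housekeeping mRNAs, 2 rose and 2 fell in Kelly, 1 fell in SKNAS and 1 in SHSY5Y (2, 2, 0 and 1 fell and 2 rose in Kelly adjusted over the list alone), and their shift had an adjusted p of 0.495, with a median of 0.01 and a mean of -0.01. In the single lines their median change was 0.01 in Kelly, 0.04 in SKNAS, -0.06 in BE2C and 0.03 in SHSY5Y.

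Large families defined by their names moved as follows. Of 531 C2H2 zinc finger genes, mostly transcriptional repressors, 365, 252, 197 and 228 fell and 2 rose, in Kelly (399, 322, 292 and 309 fell and 9, 1, 1 and 1 rose adjusted over the list alone). The list shifted down on average (adjusted p = 1.16e-78, and adjusted p = 2.71e-05 with an estimated correlation). Of 69 replication-dependent histone genes, 10, 48, 13 and 14 fell (10, 57, 22 and 30 fell and 4, 1, 2 and 1 rose adjusted over the list alone), while 4 rose in Kelly and 1 in BE2C, with adjusted p = 4.19e-17, and adjusted p = 0.0620 with an estimated correlation. HIST1H2AB fell by 0.97 ± 0.06 in SKNAS, 0.49 ± 0.05 in BE2C and 0.49 ± 0.10 in SHSY5Y. Of 12 measured members of the snoRNA host list, 7, 7, 2 and 5 fell and 1, 1, 0 and 1 rose (7, 9, 4 and 5 fell adjusted over the list alone), with adjusted p = 6.52e-07, and adjusted p = 0.0164 with an estimated correlation. The list includes NEAT1, a nuclear noncoding RNA that is not a snoRNA host, and NEAT1 was the member that rose in SHSY5Y. SNHG7 fell by 1.09 ± 0.05, 1.06 ± 0.08, 0.82 ± 0.08 and 0.50 ± 0.07. Of 2048 small nuclear and nucleolar RNA genes, 393, 211, 103 and 95 rose and 47, 78, 26 and 12 fell (396, 273, 149 and 108 rose and 47, 99, 33 and 13 fell adjusted over the list alone), with adjusted p = 6.47e-06, and adjusted p = 0.165 with an estimated correlation. Their median level, 3.32, lay below the background rows, and their median change of 0.12, 0.07, 0.10 and 0.08 was no larger than the 0.15, 0.09, 0.17 and 0.08 by which the background rows changed. RNU2-63P, a copy of the U2 gene, rose by 2.40 ± 0.08, 2.64 ± 0.10, 2.57 ± 0.09 and 2.18 ± 0.11, and RNU11, a gene of the minor spliceosome, by 1.59 ± 0.07, 1.95 ± 0.09, 1.72 ± 0.07 and 1.43 ± 0.11. Of 1109 microRNA host or precursor genes, 147, 15, 18 and 2 rose and 26, 37, 31 and 11 fell (107, 12, 18 and 1 rose and 20, 37, 34 and 5 fell adjusted over the list alone), and their shift had an adjusted p of 0.340. MIR17 fell by 1.92 ± 0.10, 1.82 ± 0.09, 0.75 ± 0.07 and 0.95 ± 0.08.

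Marker lists of other cell types served as a comparison. In Kelly 2 of 15 T cell, 0 of 10 B cell, 1 of 16 macrophage and monocyte, 1 of 9 neutrophil, 1 of 13 endothelial, 4 of 13 fibroblast and pericyte, 1 of 8 Schwann cell and 2 of 14 muscle, fat and kidney markers rose, while 1 B cell and 2 fibroblast and pericyte markers fell. Adjusted over the list alone, the markers that rose were 2, 5, 0, 0, 0, 8, 0 and 2 in that order. None of 9 adrenal cortex and 9 erythroid markers was called. In the other 3 lines the single call over these 10 lists was a fall of the fibroblast marker PDGFRA in SHSY5Y, and no list shifted in any line or on average at an adjusted camera p under 0.05. Over the 40 lists, camera called 21 lower and 4 higher in Kelly, 19 and 3 in SKNAS, 21 and 3 in BE2C, and 17 and 4 in SHSY5Y. With an estimated correlation 2, 4, 1 and 5 of these calls remained, the growth factor feedback genes in Kelly, SKNAS and SHSY5Y and the zinc finger genes in all 4 lines among them. On average over the lines 21 lists were lower and 3 higher, and 12 remained.

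**Figure D2:**
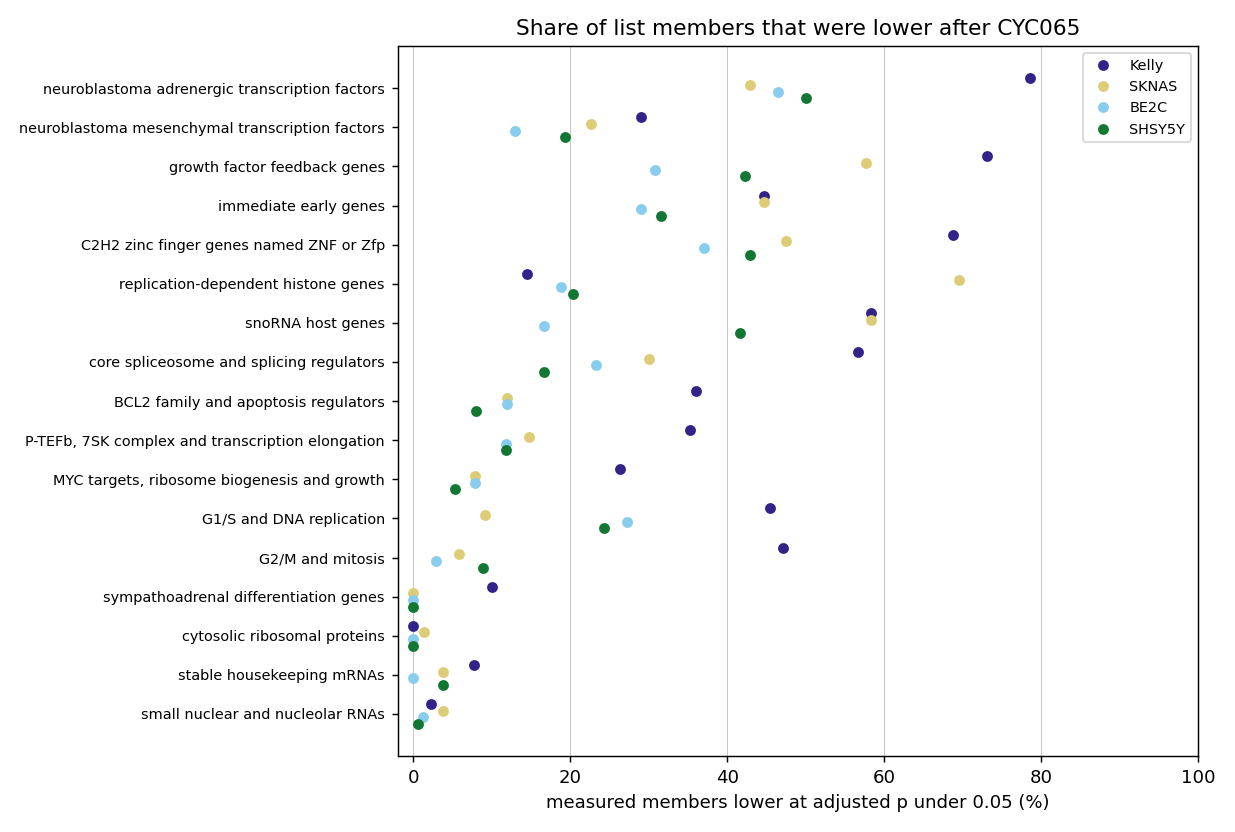
Percent of the measured members of 17 gene lists (rows) that were lower after CYC065 at an adjusted p under 0.05 (horizontal axis), with 1 point per line. The adrenergic list reaches 78.6% in Kelly and 42.9% to 50.0% in the other lines, while cytosolic ribosomal proteins, stable housekeeping mRNAs and sympathoadrenal differentiation genes stay at or below 10.0% in every line.

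The MYCN-amplified lines Kelly and BE2C were set against SKNAS and SHSY5Y to ask which responses differ between them. The errors and adjusted p values measure the spread of arrays within lines, not the spread between lines. The differences therefore hold for these lines and cannot be credited to amplification. MYCN had the most negative difference, by -1.98 ± 0.11 (adjusted p 1.55e-09), since it fell in both amplified lines and was not called in the others. RGS16, a G protein regulator, differed by -1.38 ± 0.08, PCDH18 by -1.05 ± 0.07, C2CD4A by -0.96 ± 0.09 and NRIP1, a corepressor of nuclear receptors, by -0.83 ± 0.09. ZFP36L2 differed by -0.75 ± 0.11, RGS2 by -0.72 ± 0.07, MAB21L2 by -0.78 ± 0.11, HOXD13 by -0.73 ± 0.11 and the noncoding RP11-38P22.2 by -0.82 ± 0.10. In the positive direction NFE2L3 differed by 1.83 ± 0.23, DUSP6 by 1.11 ± 0.08, the clock repressor NFIL3 by 0.93 ± 0.12, MYC by 0.87 ± 0.07 and HIST1H4B by 0.85 ± 0.10. SLITRK6, SNHG1, DNM3OS, TXNIP and RP11-439A17.10 differed by 0.73 ± 0.12, 0.73 ± 0.08, 0.71 ± 0.13, 0.68 ± 0.09 and 0.73 ± 0.15. Within the earlier deposit (Kelly minus SKNAS) and the later one (BE2C minus SHSY5Y) the difference was -2.92 ± 0.16 and -1.04 ± 0.16 for MYCN, 0.56 ± 0.09 and 1.18 ± 0.09 for MYC, -2.02 ± 0.11 and -0.75 ± 0.11 for RGS16, and 0.67 ± 0.11 and 1.55 ± 0.11 for DUSP6. For NFE2L3 it was 3.60 ± 0.32 and 0.06 ± 0.32, and for HOXD13 -1.64 ± 0.16 and 0.18 ± 0.16, so both rest on the earlier deposit. Low levels limit the MYC and MYCN differences, and the RGS2 difference in the later deposit. Untreated MYC was 5.14 in Kelly and 5.46 in BE2C, against background rows of 4.54 and 4.91. Untreated MYCN was 6.07 in SKNAS and 6.86 in SHSY5Y, against 4.58 and 4.98. Untreated RGS2 was 5.92 to 5.98 in SHSY5Y, against 4.98. A fall of MYC like that in SHSY5Y, or of MYCN or RGS2 like that in Kelly, could not be seen at these levels in full. Of the 69 histone genes, 8 had a higher change in the amplified lines (42 adjusted over the list alone) and none a lower one, with adjusted p = 4.90e-26, and adjusted p = 0.105 with an estimated correlation. Their mean change was -0.04, -0.43, -0.14 and -0.23 in Kelly, SKNAS, BE2C and SHSY5Y, so the difference rests mainly on SKNAS, whose dose is in doubt. Camera called 18 of the 40 lists for this difference, 4 up and 14 down. It called 5 up and 3 down with dim genes left out, 4 up and 0 down after quantile normalisation, 5 up and 6 down without SHSY5Y untreated replicate 3, and none with an estimated correlation. In all, 322 genes differed, 134 higher and 188 lower, and with housekeeping centring 164 were higher and 110 lower. The pairs within deposits gave 298 genes higher and 993 lower, or 1291, for Kelly against SKNAS, where the dose of SKNAS is in doubt, and 283 higher and 51 lower, or 334, for BE2C against SHSY5Y (1360 and 113 with each deposit fitted alone). As many genes or more differed when the lines were divided in either of the other possible ways, with 555 for Kelly and SKNAS against BE2C and SHSY5Y and 1143 for Kelly and SHSY5Y against SKNAS and BE2C; with array weights the 322 became 786.

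A test of any difference between the 4 lines asked which responses vary between lines, and differences between the deposits are part of it. GATA3 (F test adjusted p 1.16e-05), HAND2 (7.89e-05), HEXIM1 (0.000142), JUN (0.000441), EGR1 (0.00249), MCL1 (0.00489) and CCNE1 (0.0126) differed by the same adjusted p, and CCNT1 (0.365) was not shown to differ. In all 1710 of 30854 genes differed between lines, and 3761 with array weights.

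In the tumors the array rows carry no gene names here, so genes cannot be named. Of 65956 rows, 43971 (66.7%) changed, 32930 higher and 11041 lower, and the first principal component took 60.9% of the variance. The largest changes among called rows whose treated and untreated tumors do not overlap were falls of 4.40 ± 0.42 (log2 ± SE, n = 6 untreated and 4 treated) for TC1000001001.mm.1 and 4.07 ± 0.32 for TC1000000999.mm.1, and rises of 2.62 ± 0.14 for TC1700000496.mm.1 and 2.35 ± 0.15 for TC1600000801.mm.1. The median change over all rows was 0.25, and the deposited arrays do not share a distribution, with medians of 4.54 to 4.58 on untreated and 4.69 to 4.75 on treated arrays. In 5 groups of rows ordered by level from dim to bright the median change was 0.30, 0.31, 0.30, 0.20 and -0.12. Rows of at least 2-fold change numbered 2100, 794 higher and 1306 lower. Antigenomic background rows, which match no transcript, rose from 4.04 ± 0.07 to 5.02 ± 0.06 (mean ± SD), higher in 4 of 4 treated than in all 6 untreated tumors, with a two-sided exact permutation p of 0.00476, the smallest that 210 splits allow, and 0.0190 adjusted over 12 tests. Positive control rows fell from 8.63 ± 0.06 to 8.18 ± 0.06, with the same exact permutation p. Negative control rows changed from 4.42 ± 0.11 to 4.20 ± 0.21, with an exact permutation p of 0.0619, and 0.186 adjusted over the 12 tests. In the cell lines the background rows changed by 0.15, 0.09, 0.17 and 0.08 in Kelly, SKNAS, BE2C and SHSY5Y, and 3 against 3 arrays cannot go below an exact permutation p of 0.1. The tumor count was 27062 after cyclic loess and 28061 after quantile normalisation. The share lower, 25.1%, became 52.2% and 47.5% after these 2 and 54.8% with median centring. Only 6647 rows were brighter than nearly all of the 23 background rows, a cutoff well above the background mean, and 4525 of them were called. In the fourth of the 5 groups by level, at a median of 5.82, 6046 rows were higher and 3087 lower. In the brightest group 3116 were higher and 5649 lower.

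**Figure D3:**
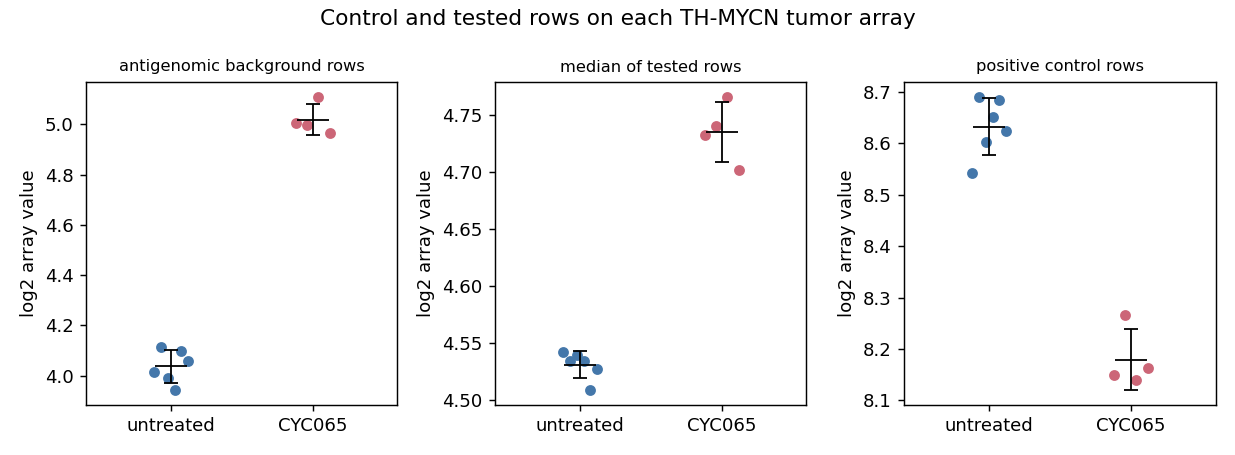
Mean log2 value of antigenomic background rows, median log2 value of all tested rows and median log2 value of positive control rows (vertical axes, not starting at 0) on each TH-MYCN tumor array, untreated or CYC065-treated (horizontal axis). Points are tumors and bars are the mean and SD; treated tumors lie higher for background rows (5.02 against 4.04) and for the median row, and lower for positive control rows (8.18 against 8.63), without overlap.

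The deposit also holds the authors' own table of changes in BE2C and SHSY5Y. At an adjusted p under 0.05 their table called 617 symbols in BE2C, 88 higher and 529 lower, and 916 in SHSY5Y, 63 higher and 853 lower. Of these, 595 and 896 are among the genes tested here, and all of them were called here too. Both sets of calls come from the same arrays, so the overlap gives no independent check. The calls here were more, 1253 and 1459. Some missed the threshold in the authors' table, such as JUN in BE2C (adjusted p 0.0574 there) and EGR1 in SHSY5Y (0.0877). The authors' fold changes and mean levels served to name the rows. For symbols matched to 1 row the sizes are therefore equal by construction and give no independent check. For the 4113 symbols matched to the mean of 2 rows the brighter row was used here, so sizes can differ.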

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

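The tests of dim genes and of MYCN amplification for the Kelly count, of background rows in the tumors, and of regrouped arrays with the shared response removed were chosen only after the result was seen, as was cyclic loess as an alternative for the tumors.

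Responses to CYC065 differed between lines by tests of the difference itself. In limma 322 genes differed between the amplified lines and the others, 1291 between Kelly and SKNAS (1360 with that deposit fitted alone), 334 between BE2C and SHSY5Y (113 fitted alone), and 1710 in any line. The differences of log2 changes, amplified minus other lines, were -1.98 for MYCN, -1.38 for RGS16, -1.05 for PCDH18, -0.96 for C2CD4A, -0.83 for NRIP1, -0.82 for RP11-38P22.2, -0.78 for MAB21L2, -0.75 for ZFP36L2, -0.73 for HOXD13 and -0.72 for RGS2. They were 1.83 for NFE2L3, 1.11 for DUSP6, 0.93 for NFIL3, 0.87 for MYC, 0.85 for HIST1H4B, 0.73 for RP11-439A17.10, 0.73 for SLITRK6, 0.73 for SNHG1, 0.71 for DNM3OS and 0.68 for TXNIP. The adjusted p of a difference in any line was 0.00489 for MCL1, 0.000142 for HEXIM1, 7.89e-05 for HAND2, 1.16e-05 for GATA3, 0.000441 for JUN, 0.00249 for EGR1 and 0.0126 for CCNE1.

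Other splits of the arrays were counted. In each line 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05; the real counts were 6524, 1968, 1253 and 1459 in Kelly, SKNAS, BE2C and SHSY5Y, and the highest other count was 0 in each. For the tumors 1 of 100 splits gave 43971 rows (highest other 0), and for the average 1 of 100 regroupings within lines gave 9162 genes (highest other 2510), so chance is excluded for both. For a difference in any line 6 of 100 regroupings gave 1710 genes or more, with up to 9263, so that count alone does not exclude chance. A count several times the real one points to a structure of the samples: exchanging labels within a line turns the shared response into a difference between lines. With the mean response of each gene removed first, 1 of 100 gave as many and the highest other was 76. For the amplified lines all 3 of the 3 possible divisions of the lines gave 322 genes or more, and 3 are too few for a share under 0.05. The division that follows the deposits gave 555 and the remaining one 1143; within the earlier and the later deposit fitted alone the difference called 1360 and 113 genes.

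Kelly had more called genes than the other lines. With the spread shared over all 24 arrays its count was 2.14 times the next highest (5999 against 2799), which argues against a smaller replicate spread as the whole cause. With dim genes left out it was 2.89 times the next highest (6278 against 2172), which argues against dim genes as the whole cause. Small shifts of brighter genes are not covered by that test. With a fold of at least 1.5 required, Kelly had 1275 genes against 667 in SKNAS, 332 in BE2C and 628 in SHSY5Y. MYCN amplification alone is argued against by BE2C, which is also amplified: its count was 1253 against 6524 in Kelly, and it stayed below that of Kelly and of SKNAS (1968) in every alternative run on all arrays of these lines. The comparison with SHSY5Y decides nothing: the BE2C count was 0.859 times that of SHSY5Y (1253 against 1459), but the larger of the pair with dim genes left out (1870 against 1659) and with trended, robust variances (1777 against 1563). Amplification together with other differences stays open, since Kelly and BE2C were measured in different deposits and the dose of SKNAS is in doubt. A stronger response of Kelly may remain as a hypothesis. The 584 genes lower in all 4 lines had a median change of -0.93 in Kelly and of -0.60, -0.50 and -0.70 in SKNAS, BE2C and SHSY5Y. These genes were picked by the calls of the same fits, so their medians give no independent support. How cells of each line were dosed and handled was not tested.

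Most tumor rows were called, 43971 of 65956. After cyclic loess, which removes a trend of change on level, 27062 were called, so a level-dependent difference between the arrays may account for part of the count. Antigenomic background rows, which belong to no comparison of genes, were 0.983 higher in treated tumors, in 4 of 4 beyond all 6 untreated, while negative control rows went from 4.42 to 4.20 (exact permutation p 0.0619). Array or RNA quality and a real change of the RNA pool at 6 h cannot be told apart, since each group was treated alike throughout.

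Rows without a gene symbol also carried signal. Of 34026 such rows, 1951 were called in Kelly, 783 in SKNAS, 161 in BE2C and 193 in SHSY5Y. Values far from the rest of their group were looked for in 18 groups of tumor values, where chance gives about 1 in 20, and 0 were found.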

How the results depend on the processing

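Cyclic loess, rows above background, identical rows counted once, and the list tests with quantile normalisation or without single replicates were chosen only after the data were seen. No named gene called in either setting changed direction with housekeeping centring, with the mean of a symbol's rows or without a single replicate. Changes of sign of genes called in neither setting were not counted. The majority direction of some counts turned.

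Requiring a fold of at least 1.5 gave 1275 genes in Kelly, 667 in SKNAS, 332 in BE2C, 628 in SHSY5Y, 612 on average, 63 for the amplified lines and 11938 tumor rows, fewer by construction. A shared spread gave 2112 in BE2C and 2799 in SHSY5Y, and array weights 4815 in SHSY5Y, 786 for the amplified lines and 3761 for any line; the cause was not tested. The average called 14854 with all rows, since more were tested, and 2940 in the later deposit alone, with fewer arrays. For the amplified lines the earlier deposit gave 1360 and the later one, BE2C against SHSY5Y, 113. Tumors gave 28061 rows after quantile normalisation and 27062 after cyclic loess. With fewer rows tested they gave 22485 with dim rows left out and 4525 among rows brighter than nearly all background rows. Of 134 list shifts, 24 stood with an estimated correlation. Those for the amplified lines, 18 (4 up and 14 down), became 8 (5 up and 3 down) with dim genes left out, 4 (all up) after quantile normalisation, 0 with an estimated correlation and 11 (5 up and 6 down) without SHSY5Y untreated 3. With dim genes left out the correlations of fold changes were 0.757 (Kelly and SKNAS), 0.764 (Kelly and BE2C), 0.822 (Kelly and SHSY5Y), 0.731 (SKNAS and BE2C), 0.741 (SKNAS and SHSY5Y) and 0.733 (BE2C and SHSY5Y); the cause was not tested. Counts of genes under the other alternatives run on all arrays stayed within 1.5 times.

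Without single replicates the counts ranged from 4174 to 6470 in Kelly, 1254 to 1916 in SKNAS, 533 to 976 in BE2C, 842 to 1749 in SHSY5Y, 40697 to 43466 in the tumors, 8301 to 10492 on average, 252 to 336 for the amplified lines, 1307 to 2077 for any line and 125 to 138 list shifts. Correlations ranged from 0.528 to 0.578 (SKNAS and BE2C), 0.593 to 0.628 (SKNAS and SHSY5Y) and 0.521 to 0.570 (BE2C and SHSY5Y). With Kelly they ranged from 0.627 to 0.665 (SKNAS), 0.576 to 0.637 (BE2C) and 0.662 to 0.743 (SHSY5Y). Arrays that moved a count by over 1.5 times were Kelly untreated 1 (4174), SKNAS untreated 2 and 3 (1254 and 1261), BE2C untreated 1, 2 and 3 (556, 645 and 533) and treated 5 and 6 (772 and 775), and SHSY5Y untreated 1 and 2 (889 and 892) and treated 5 and 6 (842 and 947). Of the named genes called, 23 of 144 lost the call without some array in Kelly, 19 of 102 in SKNAS, 30 of 97 in BE2C, 21 of 100 in SHSY5Y and 12 of 64 for the amplified lines.

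In counts on all arrays or by deposit, the larger direction turned as follows. Kelly, 2924 higher and 3600 lower, had 3905 and 3435 after quantile normalisation and 4299 and 3929 with array weights. The tumors, 32930 and 11041, had 13774 and 16673 with median centring and 12937 and 14125 after cyclic loess. They had 1612 and 2913 among the rows brighter than nearly all background rows. The average, 4958 and 4204, had 2958 and 3814 with dim genes left out, 643 and 2297 in the later deposit and 93 and 519 with a fold of at least 1.5. The amplified lines, 134 and 188, had 164 and 110 with housekeeping centring, 164 and 160 after quantile normalisation, 193 and 168 with all rows, 36 and 27 with a fold of at least 1.5 and 95 and 18 in the later deposit.

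The share lower also moved by over 10 points, without a turn, in Kelly (55.2% to 71.4% with median centring, 65.7% after cyclic loess and 84.4% with a fold of at least 1.5), BE2C (82.0% to 68.4% with housekeeping centring and 71.5% with a shared spread) and SHSY5Y (90.9% to 63.6% with array weights and 80.4% with a shared spread). It did so for the amplified lines in the earlier deposit (58.4% to 75.7%) and for the tumors (25.1% to 47.5% after quantile normalisation, 43.4% with dim rows left out and 39.2% with a fold of at least 1.5). In the tumors median centring, quantile normalisation and cyclic loess shifted the median row by -0.20, -0.21 and -0.23; the cause of the other moves was not tested.

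No paired analysis was possible because the groups compared share no replicate numbers. Housekeeping centring and the mean of a symbol's rows were not run for the mouse, whose rows carry no names here. Signal over background limits dim genes: background rows averaged 4.54 in untreated Kelly, against a median gene of 5.38.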

Other observations

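The tests of the small nuclear RNA genes below were chosen only after the result was seen.

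The 45 small nuclear RNA genes higher in all 4 lines had median rises of 0.94 in Kelly, 1.03 in SKNAS, 0.68 in BE2C and 0.52 in SHSY5Y, and 40 of the 45 were still called in all 4 lines after centring on housekeeping genes. They are 21 of 99 measured U1, 6 of 8 U1 variant, 9 of 69 U2, 3 of 89 U4, 3 of 30 U5, 1 of 6 U11, 1 of 2 U12 and 1 of 18 U4atac genes, against 0 of 157 U7 genes. In families transcribed by RNA polymerase II 45 of 479 genes rose in all 4 lines and in the U6 families, transcribed by polymerase III, 0 of 1279 (Fisher exact p 8.11e-27, with genes that are not independent). Most of these genes are dim, with a median level of 3.34 and 3.10, below the background rows, and 216 and 132 of them were higher in at least 1 line. Among genes whose untreated mean was above 5.08, the highest background mean of a group, 34 of 103 and 0 of 148 were higher in all 4 lines (Fisher exact p 1.55e-15) and 84 and 34 in at least 1, at median untreated levels of 6.30 and 6.10. So a rise of the array background is argued against for these 34, since it would raise the U6 genes above background too. The levels given are medians of all 103 and 148 genes, not of the 34. The 45 that rose had a median level of 7.38 over all arrays, so levels were not matched gene by gene. For the remaining 11 of the 45, at or below 5.08, it stays open, because they lie near the floor. The rise in all 4 lines was seen in families transcribed by polymerase II and not in all of them: of the 157 U7 genes, also counted there, 10 were higher and 29 lower in at least 1 line. How many source RNAs rose stays open: 45 of 45 belong to families with several similar copies, and probe sequences were not used here. Whether each named copy is itself transcribed was not tested. Nor was how well RNAs of each family were recovered in purification, so the contrast cannot be put down to the polymerase.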
